A study of Homo sapiens with 801 samples.

How the data were processed

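Single cells of WM989-A6G3, a human melanoma cell line grown without treatment, were profiled by Drop-seq, in which cells and barcoded beads are paired in droplets, and on the Fluidigm C1 HT integrated fluidic circuit, a chip that captures cells at sites laid out in columns (called C1-HT here). RNA FISH, the other platform named in the study's design, was not analysed here. The labels name 1 Drop-seq sample and 800 C1-HT capture sites. They name no separate cultures, so each platform was treated as 1 sample, no test between platforms was run, and no p-value is given. Intervals are exact Poisson intervals for pooled counts and exact binomial (Clopper-Pearson) intervals for shares of cells, at the 95% level, and cover counting error only. Spread over the 10 C1-HT columns with at least 20 sites each is given as an SD. These are columns 1 to 10. Pooled C1-HT levels also include the 65 sites of columns 11 to 19, which the SD does not cover. The SD was taken as technical spread within a platform, which was not tested. The site titles carry a sample number per column and do not say what it stands for.

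The authors deposited a table of counts per gene and cell for each platform, and a table of the same cells in RPM. Drop-seq libraries followed protocol v3.1 of its developers and C1-HT libraries the manufacturer's instructions, per the labels. STAR 2.4.2a and the genome builds hg38 and mm10 are named in the submitters' processing notes. A comment in the header of the Drop-seq table records a selection of cells without its criteria. The counting tool, the gene annotation, the use of molecular identifiers and the rule by which barcodes or sites were kept are not given in the sources used here, so C1-HT counts may be reads and Drop-seq counts molecules. The Drop-seq table of counts held 32287 genes in 8640 barcodes and the C1-HT table of counts 24427 genes in 335 sites. The deposited RPM values equalled counts divided by the cell's total to within 6e-10, so the counts were used for all main values.

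Pooled levels are counts summed over all cells and divided by the total, on the scale of the RPM values (CPM). Levels were correlated across genes as log2(CPM + 1) over genes with at least 10 counts on each platform. Ratios were computed for genes with at least 20 CPM on either platform and at least 10 counts over both, with counts under 3 raised to 3. Cell-to-cell variation was measured in cells with at least 1000 genes detected, as the Gini coefficient of per-cell CPM (0 for equal levels, 1 for all counts in 1 cell) and as the gene's percentile among the 200 genes nearest in mean CPM. Shares of cells with a count were taken after each cell was thinned to 2000 counts, and also unthinned. Co-detection compared the number of cells with at least 2 resistance genes, each detected in under 20% of cells, with the number expected when genes are placed independently with a chance that scales with the cell's depth. Correlation within a gene list was the median pairwise Pearson correlation of log2(CPM/100 + 1) over cells, set against 10000 random lists of the same size matched on mean level. Drop-seq cells were clustered on 2000 variable genes, 20 principal components and 15 neighbours with the Leiden algorithm at resolution 0.5. All cells came from 1 cell line, no doublet caller was run, and doublets were not removed.

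Gene numbers at a fixed depth are given per 100 counts and numbers of genes apart mostly as a percent of the genes compared. The groups, designs, alternatives and gene lists were fixed before the data were examined. The lists were resistance, melanocytic, housekeeping, S-phase, mitotic, histone, immediate early and heat shock, hypoxia, integrated stress response, interferon, matrix, fibroblast, keratinocyte, immune and endothelial genes. Named genes were any list member, the 12 genes with the largest ratio in each direction at 50 CPM or more and at least 10 counts on the lower platform, the 15 genes with the highest Gini excess over the 200 genes nearest in level at 50 CPM or more and at least 20 cells with a count, and the 10 genes highest by fold in each cluster. Some genes of this rule that have clone names only are not named. Gene positions and classes are those of GENCODE release 29 on GRCh38, found by symbol, which matched 67.5% of Drop-seq and 72.3% of C1-HT gene names. Genes that share sequence with pseudogenes or paralogs have uncertain levels, because the treatment of reads that match several places is not given in the sources used here.

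The alternatives covered the depth of thinning, the filter on cells, pooling, scaling, the pseudocount, the filter on low levels, subsets of the C1-HT columns, the form of the expected number in co-detection, cluster resolution and clustering without cell cycle genes. Restrictions to protein-coding genes, to columns 1 to 10 and to columns 11 to 19, and other level filters for the early gene list, were added after the data were seen. Where an explanation was tested against matched random lists, the test was left open if under 80% of the genes had a value, or if the value lay within 1 SD, over 1000 bootstrap draws of the genes, of its bound. The SD margin was added after the first values were seen, and was applied to every such test on both sides of the bound.

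The scripts were tested on simulated data. For the comparison of levels, 90 of 100 genes simulated with 8-fold differences and 0 of 100 with 2-fold differences were called at least 4-fold apart, as were 0 unchanged genes, among 6575 genes. For the Gini percentiles, 20 of 20 genes placed in a subset of cells were found. For co-detection, 30 simulated cells with several of 12 equally rare genes raised the median ratio to 1.21, against 0.966 for independent genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.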

Results

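The data were single-cell gene counts from WM989-A6G3, a human melanoma cell line, measured by Drop-seq and on C1-HT in order to compare expression estimates between platforms, with the study of rare cells as the stated purpose. Drop-seq gave 22404792 counts in 8640 barcodes, with a median of 1156 counts (range 74 to 100681) and 710 genes. C1-HT gave 49789180 counts in 41.9% of the 800 labelled sites, with a median of 123471 counts (range 13169 to 900247) and 3909 genes. At least 1000 genes were detected in 2267 Drop-seq barcodes, which held 69.4% of the counts, and in 99.4% of the C1-HT sites. Mitochondrial genes took 12.5% of Drop-seq and 36.5% of C1-HT counts. Each platform was treated as 1 sample, so no difference between them has a replicate check.

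The first comparison asked how many genes each platform detected per cell. At an equal 2000 counts per cell, the median was 59.3 genes per 100 counts in Drop-seq (quartiles 54 and 61.8, 2089 cells), or 1185 genes, and 39.2 on C1-HT (quartiles 36 and 41.98). The 6551 Drop-seq barcodes with fewer counts were left out, and no C1-HT site was. The order was the same at 1000 counts (65.5 and 47.2 genes per 100 counts) and at 5000 counts (46.7 and 27.4). Equal counts were not equal in kind, since mitochondrial genes took 12.5% of Drop-seq and 36.5% of C1-HT counts. C1-HT counts may also be reads and Drop-seq counts molecules, so this order does not rank the platforms by sensitivity. Within C1-HT and unthinned, the 270 sites of columns 1 to 10 had a median of 3828.5 genes and the 65 sites of columns 11 to 19 had 5045. Their depth differed too, with medians of 112778 and 184017 counts.

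The second comparison set gene levels on the platforms side by side. The melanocytic program was abundant on both. PMEL, a structural protein of pigment granules, stood at 5118 CPM in Drop-seq and 2605 on C1-HT (mean of columns 2303 ± 436.5, SD, n = 10), and MLANA, a melanocyte antigen, at 1997 and 4024 CPM. MITF, the master transcription factor of the lineage, stood at 454.4 and 679.2 CPM, SOX10, a neural crest transcription factor, at 85.1 and 203.6 CPM, and S100B, a calcium-binding protein, at 651.6 and 1456 CPM. Several immediate early genes, which cells switch on within minutes of a stimulus, were higher on C1-HT, while many processed pseudogenes and several housekeeping genes were lower.

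Across 15346 genes, pooled levels had a Pearson correlation of 0.845 and a Spearman correlation of 0.824; these are across genes, which are not independent replicates. Of 6950 genes compared, 1.45% were at least 4-fold higher and 13.2% (914 genes) at least 4-fold lower on C1-HT, so that 9.95% of the genes apart were higher. The median log2 ratio of C1-HT over Drop-seq was -0.60. Relative to that median, 4.29% were higher and 9.21% lower, and 31.8% of the genes apart were higher. Of the higher genes, 87.1% exceeded the Drop-seq level in each of the 10 columns, and 911 of the 914 lower genes lay below it in each. Of the 6009 protein-coding genes compared, 1.43% were higher and 6.31% lower.

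**Figure D1:**
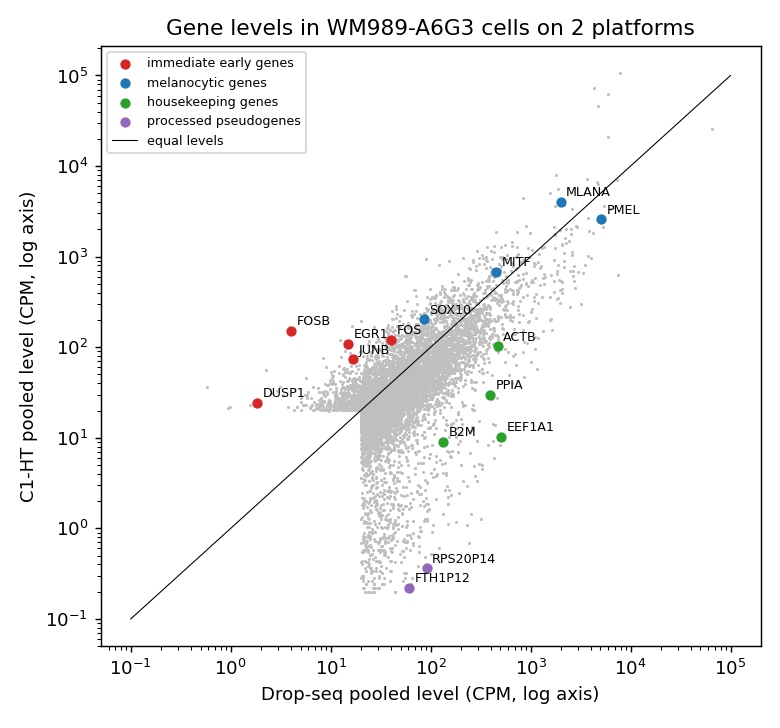
Pooled level in CPM on C1-HT (vertical log axis) against Drop-seq (horizontal log axis), 1 grey point per compared gene with at least 10 counts on each platform, with listed genes in colour and a line of equal levels. FOSB stood at 4.02 CPM in Drop-seq and 151.7 CPM on C1-HT, above the line, and EEF1A1 at 510.7 and 10.3 CPM, below it.

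Among genes at 50 CPM or more, the largest ratio in favour of C1-HT belonged to FOSB, a subunit of the AP-1 transcription factor (chromosome 19, 45467995 to 45475179, GRCh38). It stood at 4.02 CPM in Drop-seq (interval 3.23 to 4.94) and 151.7 CPM on C1-HT (mean of columns 148.8 ± 23.15, SD, n = 10), a 37.8-fold difference. Of the listed early and heat shock genes, 9 had at least 20 CPM on either platform, and 4 of these were at least 4-fold higher on C1-HT, all of them under 20 CPM in Drop-seq. The median log2 ratio of the 9 was 1.58, or 2.18 relative to all genes, at percentile 99.99 of random lists matched on both platforms and 99.85 of lists matched on Drop-seq level. All 13 members in both tables had a median log2 ratio of 0.68, or 1.59 relative to genes under the same filter (percentile 99.9), with 10 above the median and IER3 at least 4-fold lower. The 5 members with at least 20 CPM in Drop-seq had a relative median of 0.57 (percentiles 69.6 and 85.6). IER3 had 1 count on C1-HT, a ratio of 0.00398 (interval 9.99e-05 to 0.0226). The ratios of BTG2, ZFP36 and IER2 were 0.434, 0.772 and 0.908, and that of ATF3 was 2.44. EGR1, an early growth response transcription factor, stood at 14.95 and 109.7 CPM (C1-HT columns 110.95 ± 26.6), and JUNB, another AP-1 subunit, at 16.9 and 74.1 CPM (columns 71.8 ± 21.01). DUSP1, a phosphatase that dampens MAP kinase signalling, stood at 1.83 and 24.5 CPM (columns 24.9 ± 12.4). FOS was 2.99-fold higher on C1-HT, at 40.5 and 121.1 CPM (columns 123.6 ± 19.6). MYC, a growth-promoting transcription factor, went the other way, at 227.5 CPM in Drop-seq and 63.97 on C1-HT, and the chaperone gene HSPH1 stood at 185.5 and 170.4 CPM.

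**Figure D2:**
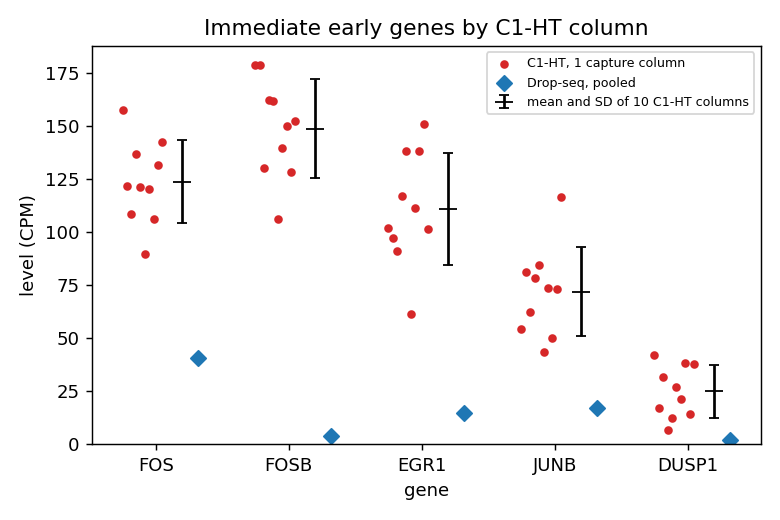
Level in CPM of 5 immediate early genes, chosen after their levels were seen, in each of the 10 C1-HT columns with at least 20 sites (red points), their mean and SD (black), and the pooled Drop-seq level (blue diamonds). Each column lay above the Drop-seq level for FOS, FOSB, EGR1, JUNB and DUSP1.

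The other genes with the largest ratios toward C1-HT were SND1-IT1, an intronic transcript (25.3-fold), ECI2, an enzyme of fatty acid oxidation (11.2-fold), DIP2C (10.5-fold) and TEX261 (9.72-fold), a gene with a clone name only (10.9-fold), and genes of mitochondrial origin. MT-CYB, a subunit of respiratory complex III, was 16.7-fold higher and MT-ND4, a subunit of complex I, 13.6-fold higher. MT-ATP6 and MT-CO2, subunits of ATP synthase and cytochrome oxidase, were 10.4-fold and 9.88-fold higher. The nuclear pseudogenes MTND4P12 and MTATP6P2, near-copies of mitochondrial genes, were 10.5-fold and 9.54-fold higher, with uncertain levels because of that shared sequence.

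The 12 largest ratios toward Drop-seq ranged from 191.6-fold to 352.4-fold. They included processed pseudogenes, intronless gene copies, of ferritin (FTH1P12, 276.6-fold), the growth-associated protein TPT1 (TPT1P9, 263.9-fold), ribosomal proteins (RPS20P14, 253.3-fold, RPS23P1, 204.96-fold, and RPL30P14, 195.4-fold), elongation factor 1 (EEF1A1P13, 233.7-fold) and the RNA-binding protein YBX1 (YBX1P1, 201.3-fold, and YBX1P10, 191.6-fold). The other 4 had clone names and no GENCODE 29 match. Of the 914 lower genes, 72.98% had a class in that annotation, and 39.9% of these were processed pseudogenes, against 4.36% of the compared genes with a class. Levels of these pseudogenes and of their parent genes are uncertain.

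Housekeeping genes split. Of 19 compared, 4 were at least 4-fold lower on C1-HT, and the list median of -0.59 lay at percentile 29.6 of random lists. EEF1A1, a translation elongation factor, stood at 510.7 CPM in Drop-seq and 10.3 on C1-HT (49.5-fold lower), B2M, the light chain of MHC class I, at 134.3 and 9.08 CPM (14.8-fold), PPIA, a prolyl isomerase, at 393.3 and 29.8 CPM (13.2-fold), and ACTB, cytoplasmic actin, at 467.4 and 102.8 CPM (4.55-fold). GAPDH, a glycolytic enzyme, went the other way, at 3699 and 7212 CPM. Of 15 melanocytic genes compared, 3 were at least 4-fold lower on C1-HT, namely S100A1 (9.47-fold), CAPN3 (7.48-fold) and SLC45A2 (6.09-fold). No S-phase gene (18 compared), hypoxia gene (7), interferon gene (4) or matrix gene (3) differed 4-fold. Of the integrated stress response genes, 1 of 9 did, HSPA5, an endoplasmic reticulum chaperone (4.05-fold lower), as did HMGB2 among 20 mitotic genes (6.41-fold lower) and HIST1H4C and HIST1H1D among 5 histone genes (4.33-fold and 9.91-fold lower). A single resistance gene (FOSL1), fibroblast gene (LUM) and keratinocyte gene (KRT10) passed the minimum level, with ratios of 1.94, 1.23 and 2.21, and no immune or endothelial gene did. The medians of the other lists lay between percentiles 10.3 and 94.1 of random lists, apart from percentile 97 for KRT10 alone.

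The third comparison asked which genes varied most from cell to cell. The median Gini percentile of mitotic genes among genes of like level was 98 in Drop-seq, where 18 of 20 reached the 90th percentile, and 96 on C1-HT, where 14 of 19 did. S-phase genes had medians of 89.3 and 69.3, integrated stress response genes 94 and 68, and histone genes 98 and 93.8. Housekeeping genes had low medians of 33.5 and 35. Melanocytic genes had 69.8 and 42, immediate early and heat shock genes 86 (5 genes) and 26 (9 genes), and interferon genes 81.3 and 85. Hypoxia genes had 92.5 and 59, and matrix genes 84.5 (2 genes) and 28 (3 genes). The resistance gene FOSL1 had 93.5 and 89.5, LUM 23.5 and 48, and KRT10 44 and 49.5.

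VGF, a secreted neuropeptide precursor, had the largest Gini excess in Drop-seq, with a Gini of 0.768 against 0.328 from Poisson sampling, and was detected in 57.9% of cells. On C1-HT its Gini was 0.820, in 80.5% of sites. Next in Drop-seq came MKI67, a proliferation marker (0.740), CENPF, a kinetochore protein (0.699), NEAT1, a nuclear noncoding RNA (0.700), and HIST1H4C, a replication-dependent histone (0.624), and then HSPA5, ASPM, TOP2A and DCT, a pigment enzyme (0.622). The list also held SAT1 and the mitochondrial or mitochondria-like genes MT-RNR1, MTRNR2L1, MTATP6P1 and MT-ND6, and a gene with a clone name only. On C1-HT the first was ISG15, an interferon-induced ubiquitin-like protein (0.778), followed by VGF, DNAJC3, CHD1, UCN2, NEAT1 (0.544), MRPS27, HIST1H4C (0.665), STK4, SMC2, ACAT1, TPX2, UBE2C, ZBED4 and MED7.

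Across 4499 genes, Gini percentiles on the platforms had a Spearman correlation of 0.179, or 0.0999 at 2000 counts per cell. At or above the 95th percentile lay 4.51% of these genes in Drop-seq, 4.69% on C1-HT and 33 genes on both, against 9.52 if the lists were independent. The 33 included VGF, NEAT1, DCT and SAT1, the cell cycle genes MKI67, CENPF, TPX2, UBE2C, TOP2A, CCNB1, AURKA and RRM2, the interferon-induced genes ISG15 and IFIT3, and DDIT3, a stress transcription factor.

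The fourth comparison concerned rare transcripts of drug resistance, the kind of gene followed in rare cells of this line. At 2000 counts per cell, any of the resistance genes was seen in 11.3% of Drop-seq cells (interval 10.02 to 12.8) and 14.9% of C1-HT sites (11.3 to 19.2). The sets differed, with AXL in Drop-seq only and CYR61 on C1-HT only. JUN stood at 3.88 CPM in Drop-seq and 17.2 on C1-HT, 4.43-fold higher. In sites with at least 1000 genes, FOSL1, JUN, FGFR1 and RUNX2 were seen in 42.04%, 27.3%, 17.4% and 15.02%. The shares for any gene are therefore not shares of cells with a rare marker. Unthinned, FOSL1, an AP-1 subunit, was seen in 5.38% of all Drop-seq barcodes and 41.8% of sites, and JUN in 0.741% and 27.2%. EGFR, a growth factor receptor, was seen in 0.486% and 3.88%, and NGFR, the nerve growth factor receptor, in 0.0694% and 0.896%. In the 10 columns with at least 20 sites, NGFR and VEGFC had a mean of 0 CPM. All C1-HT sites with either gene thus lay in columns 11 to 19, whose sites had a higher median depth. At 2000 counts, EGFR was seen in 0.479% of Drop-seq cells (0.230 to 0.879) and in 0 C1-HT sites. A limit of 3 counts, 0.896% here, bounds the share of sites with a count at that depth and not the share of cells that express the gene. NGFR was seen in 0.0957% of Drop-seq cells (0.0116 to 0.345) at 2000 counts. AXL, a receptor kinase, had a count in 2 of 8640 Drop-seq barcodes. As a background, any immune gene was seen in 0.431% (0.197 to 0.816) and any endothelial gene in 0.191% of Drop-seq cells at 2000 counts, and neither in any C1-HT site. The fibroblast gene LUM and the keratinocyte gene KRT10 were seen in 9.14% and 5.27% of Drop-seq cells and in 8.66% and 11.3% of sites, and any matrix gene in 48.9% and 34.03%. No cell type lacking the resistance genes was there to measure free RNA in.

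Counted over the whole list and with chances scaled by depth, cells with at least 2 resistance genes were no more frequent than independent placement gave. In Drop-seq, the observed number was 0.893 of the 119.9 cells expected (interval 0.731 to 1.08), and on C1-HT 29 were observed and 29.6 expected, a ratio of 0.978 (0.655 to 1.41). The gene sets differed: 13 genes in Drop-seq, and 12 on C1-HT, without JUN and FOSL1 and with CYR61. With no scaling by depth the Drop-seq ratio was 1.30 (1.06 to 1.57), and with at least 2 counts of each gene it was 1.80 (0.899 to 3.22). In simulated data of 12 equally rare genes, 30 cells with several of them gave a median ratio of 1.21, and smaller groups were not simulated. The real Drop-seq set holds more common genes, with FOSL1 in 12.4%, FGFR1 in 9.40% and RUNX2 in 5.78% of cells. The 1.21 therefore does not show what 30 such cells would give here. FGFR1 and FOSL1 were seen together in 36 Drop-seq cells, FOSL1 and RUNX2 in 27, and FGFR1 and RUNX2 in 20. The count thus says little about the rarest genes. On C1-HT, pairs picked after their values were seen went both ways. NGFR and RUNX2 were together in 3 sites (0.661 expected), and FGFR1 and RUNX2 in 8 (12.08 expected). The intervals of both ratios held 1.

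The fifth comparison asked which gene groups moved together across cells. Mitotic genes had a median pairwise correlation of 0.257 in Drop-seq and 0.364 on C1-HT, S-phase genes 0.189 and 0.212, and integrated stress response genes 0.145 and 0.190, each above all 10000 random lists. Histone genes (0.0939 and 0.119), hypoxia genes (0.0438 and 0.0690) and interferon genes (0.0577 and 0.0958) lay at percentile 98.1 or higher on both in the main setting. These calls depended on the setting: with a minimum of 500 genes, histone genes lay at percentile 88.2 and interferon genes at 18.9 in Drop-seq. At 2000 counts per cell, histone genes lay at 85.9 and hypoxia genes at 73.2 on C1-HT. Immediate early and heat shock genes had 0.0585 in Drop-seq, at percentile 96.95 (91.05 with a minimum of 500 genes), and 0.111 on C1-HT, above all random lists. The sets were unlike: 5 genes in Drop-seq (FOS, IER2, MYC, DNAJB1 and HSPH1), and 9 on C1-HT, which add FOSB, EGR1, JUNB and DUSP1. At 2000 counts per cell these genes lay at percentiles 99.98 and 95.8. Melanocytic genes did not stand apart, at 0.0242 (percentile 23.8) and 0.0523 (percentile 88.7). Housekeeping genes had 0.0588 (percentile 92.01) and 0.0670 (percentile 99.7, or 93.8 at 2000 counts per cell).

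Clustering of the 2267 Drop-seq cells gave 5 clusters. An S-phase-like cluster of 19.9% of cells was led by CCNE2, GINS2, MCM10, EXO1 and DTL, genes of replication and its onset. A mitotic-like cluster of 11.9% was led by the early gene EGR1 and then by CCNB1, NEK2, DLGAP5 and PLK1. The other clusters were not named. Cluster 1 (29.4%) was led by PNRC1 and SNHG18, and its mitotic genes had a median fold of 0.147 against the other cells. Cluster 2 (24.9%) was led by PIF1 and held NEAT1 and MT-RNR1, with 32.1% mitochondrial counts against 7.29% to 11.99% in the others. Cluster 4 (13.9%), led by SPATA22, had a median of 2048 counts. No cluster was led by melanocytic or interferon genes. Too few resistance genes reached 20 CPM in any cluster for that list to be scored. A resistance-like cluster could therefore not have been called, and its absence decides nothing.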

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

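The restrictions to protein-coding genes, to columns 1 to 10 and to columns 11 to 19, and the filters on the early gene list, were chosen after the data were seen. The order of the platforms in genes per cell held at every thinning depth, while the medians moved to 65.5 and 46.7 genes per 100 counts in Drop-seq and to 47.2 and 27.4 on C1-HT at 1000 and 5000 counts. The level correlation of 0.845 ranged from 0.823 to 0.894: it was 0.887 with no filter on counts, 0.830 for the mean of per-cell CPM (also 0.830 for the authors' values), 0.824 and 0.866 with pseudocounts of 0.1 and 10, 0.831 and 0.834 in odd and even columns, 0.894 for protein-coding genes, and 0.837 and 0.823 in columns 1 to 10 and 11 to 19. The genes apart, 14.6% of 6950 compared (1.45% higher, 13.2% lower), were 13.8% of the 2061 compared at a minimum of 100 CPM (2.18% higher, 11.6% lower) and 7.74% of the 6009 protein-coding genes (6.31% lower), so that their number dropped by over 1.5 times. The share higher on C1-HT was 2.72% of 8184 genes without mitochondrial and ribosomal protein genes in the totals and 4.29% relative to the median ratio. The Gini correlation was 0.0999 at 2000 counts per cell and 0.259 at a minimum of 100 CPM. The mitotic Gini percentile dropped to 87.5 in Drop-seq with no filter on cells and to 84.5 on C1-HT at 2000 counts per cell. The share of cells with any resistance gene followed depth, with 5.47% and 24.2% of Drop-seq cells and 9.55% and 27.8% of C1-HT sites at 1000 and 5000 counts, and 71.04% of sites unthinned. The Drop-seq co-detection ratio was 1.30 with no depth scaling, 0.679 for at least 3 genes and 1.80 for at least 2 counts. The melanocytic correlation on C1-HT reached percentile 95.3 with a minimum of 500 genes. The correlation within hypoxia genes on C1-HT lay at percentile 66.9 in columns 1 to 10. The early gene list's median log2 ratio relative to all genes, 2.18, was 0.57 for members with at least 20 CPM in Drop-seq. Clusters numbered 10 at resolution 1.0. Apart from thinning, depth scaling and the numbers of genes compared, the cause was not tested. Among all values for these results, 94 stayed within their margin, 33 moved, 1 grew stronger and 2 weaker. Some of the 94 could not move, since the authors' values equal the scaled counts. No named ratio of at least 4-fold changed sign. No paired analysis was possible because each platform was treated as 1 sample. Depth limits the shares of rare genes.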

Other observations

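Tests chosen only after the result was seen were the co-detection of resistance genes as a hypothesis, the interferon count with at least 3 genes, the pseudogene shares that counted pseudogenes themselves or protein-coding genes alone, the transcript lengths of protein-coding genes, the use of FOS, FOSB, EGR1, JUNB and DUSP1 in place of the whole early gene list, and the early gene test matched on the mean of both platforms, the early gene list under other level filters, under other totals, in deep cells and in each column, the lower genes followed one by one under other totals, and the spread between shallow barcodes, as was the margin of 1 bootstrap SD that left tests near their bound open.

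When cell cycle genes were left out of the clustering, a stress-like cluster of 15.6% of Drop-seq cells appeared, in which 3 of the 10 leading genes belonged to the integrated stress response list (DDIT4, HSPA5 and HERPUD1). It was led by RGS1, PNRC1, NRN1 and NUPR1, and its listed stress genes had a median fold of 1.80. Its interferon and hypoxia genes had median folds of 1.51 and 1.38. Its mitotic, S-phase and histone genes were lower than in the other cells, with median folds of 0.240, 0.438 and 0.383, and PNRC1 and NRN1 also led cluster 1 of the main clustering. The cluster rich in mitochondrial counts was found again, with 32.3% mitochondrial counts and NEAT1 among its leading genes. A cluster of 12.8% of cells led by CDCA8 and CCNA2 had median folds of 2.64 for mitotic and 1.90 for S-phase genes. The cell cycle was thus not fully removed.

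Among early response genes outside the fixed list, 12 of 25 could be compared, and those named here were picked after their values were seen. NR4A2, a nuclear receptor, was 11.7-fold higher on C1-HT (3.12 and 36.6 CPM), TRIB1, a pseudokinase, 4.82-fold (10.4 and 49.9 CPM) and IER5 3.64-fold. DUSP4, DUSP6, PPP1R15A and NFKBIZ stood lower on C1-HT, at 0.541, 0.808, 0.284 and 0.618 of the Drop-seq level. Of the 12, 9 had a log2 ratio above the median of all compared genes (-0.60), and 2 were at least 4-fold higher on C1-HT.

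The higher level of immediate early genes on C1-HT was weighed against technical causes. Scaling by mitochondrial reads was argued against by its direction alone. Mitochondrial genes took 12.5% of Drop-seq and 36.5% of C1-HT counts. Leaving them out of the totals therefore raised the log2 ratio of every other gene by the same 0.46. The median of all 13 members went from 0.68 to 1.14 by that shift, which is not particular to the list. The 2.18 relative to all genes, the test set in advance, decides nothing here, since a change of totals cannot move it. For all 13 members, a few odd columns were argued against by a list median above that of all genes in 10 of 10 columns (relative median 0.24 to 1.75), and free RNA in shallow barcodes by a relative median of 1.51 with only Drop-seq cells of at least 2000 genes; the values of FOS, FOSB, EGR1, JUNB and DUSP1 (10 of 10 columns, and 2.83 in these cells) decide nothing, since they are the list's highest ratios. Induction during capture may contribute but stays open: the median log2 ratio of the other early genes was 0.52 ± 0.53 (bootstrap SD), under the bound of 0.56 set in advance from random lists matched on Drop-seq level, and over a bound of 0.18 when lists were matched on the mean of both platforms. Different cultures, handling times or chemistry were not tested.

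For the 914 genes lower on C1-HT, scaling by mitochondrial reads was argued against, as was scaling by ribosomal protein reads: without both classes in the totals 902 of 8184 genes compared were lower, and 78.5% of the 862 original members outside these classes stayed at least 4-fold lower. Tests over all of these genes were void, since only 72.98% had an annotated class and 73.1% a length. Those set in advance gave 17.1% with a processed pseudogene (percentile 42.03 of random lists) and a median length of 1700.5 nt, and one chosen afterwards gave 56.97% that are or have one. Among the protein-coding members, 30.1% had a processed pseudogene, over a bound of 25.9%. Reads shared with pseudogenes, if handled differently on the platforms, may therefore account for part of the set. How reads were handled was not measured. Over all protein-coding genes compared, the median log2 ratio differed little, at -0.62 with a processed pseudogene and -0.47 without. A loss of short transcripts stays open, because the median length of 3252 nt among protein-coding members and of 3492 nt among those without a pseudogene lay within 1 SD (120.96 and 150 nt) of the bounds of 3241 and 3516 nt, on opposite sides, and no biological explanation was tested.

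The Drop-seq barcodes with under 1000 genes may hold free RNA rather than cells, which stays open. At 700 counts per barcode, the median pairwise correlation of mitotic genes was 0.00679 in 6044 of these barcodes and 0.0737 in the 2267 deeper ones, a ratio of 0.0921. It lay under the bound set in advance, which argues against smaller cells that divide like the others and goes with free RNA. The spread of 500 abundant genes between barcodes was set against what independent draws from 1 shared pool of RNA give. As a multiple of that, it was 1.18 in the shallow barcodes and 1.11 in the deeper ones (bootstrap SD 0.00295 and 0.0034). The use of molecular identifiers is not given, and repeated counts of 1 molecule would also raise this spread. The deeper barcodes were also thinned further. These values therefore do not exclude a shared pool. Pooled levels of both sets of barcodes had a correlation of 0.956 across 7031 genes, and quiescent cells were not separated from free RNA.

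A small group of cells with a joint interferon response was tested as a hypothesis in Drop-seq. The planned count, cells with at least 2 of 9 rare interferon genes, gave 50 observed and 42.2 expected, a ratio of 1.19 (interval 0.880 to 1.56), which did not exceed independent placement. Cells with at least 3 numbered 18 against 4.60 expected, a ratio of 3.91 (2.32 to 6.18). On C1-HT, with 8 genes and IFIT3 not among them, that ratio was 1.40 (0.0355 to 7.81), from 1 site. A few cells with several of these genes may therefore exist in Drop-seq, and this rests on a count chosen after the planned one. The like hypothesis for resistance genes found no excess over the whole list when scaled by depth, with a ratio of 0.893. That count held many pairs of the more common FOSL1, FGFR1 and RUNX2, so it says little about the rarest genes.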
